A study of Homo sapiens with 3 samples.

How the data were processed

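RNA bound by CSTF2tau, an RNA-binding subunit of the cleavage stimulation factor, was measured by sCLIP in BE(2)-C cells, an established human neuroblastoma line. In this method, ultraviolet light crosslinks protein to RNA in living cells, the RNA is partly digested, and the fragments recovered with an antibody are sequenced. The labels give 1 group of 3 biological replicates of unmodified cells. No input or control antibody library was used here, so every comparison was made between replicates or within a library.

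Each replicate has 1 list of peaks with 8 columns and no header. The columns hold the chromosome, start, end, a name, a p-value, the strand and the edges of a stretch of at most 4 nt inside the peak. Per the submitters' processing notes the genome build was hg19, and the notes name FastQC, SAMtools, STAR and bedtools without versions or roles. The peak caller, its settings and the annotation were not given in the sources used here. The p-value of each peak is the authors' own as deposited, stayed below 0.05 in every list, and was used to filter peaks within a list and to read the peak names. The name joins an Ensembl gene ID, a running number and a whole number of at least 3 in the authors' deposited lists. This last number was read here as the reads in the peak, because across peaks its Spearman correlation with the p-value was -0.988, -0.973 and -0.964 in replicates 1, 2 and 3. No source states this reading, and every read value rests on it. Peaks were listed per replicate, not on pooled replicates.

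The lists held 105203, 18346 and 78761 peaks with 736059, 108434 and 387784 reads. These totals cover only reads inside listed peaks and are not the sequencing depth. Intervals at the 95% level are exact Clopper-Pearson intervals. They cover counting error only, because the listed reads need not be independent molecules. No source used here states whether the number in the peak name counts reads or unique fragments. Overlapping peaks on the same strand were merged into clusters within a replicate and into loci over all 3 replicates. Some peaks were listed under several gene IDs, and such a cluster or locus took its reads from the ID with the most. Every listed line was used for totals, for shares per gene ID, chromosome or strand, and for the joint share of loci in all 3 replicates. Among these, 3371, 795 and 3378 lines repeat the coordinates of another. Locus shares were divided by these totals.

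Before the data were examined, the design, the gene lists, the rule for named items and a set of alternatives were fixed, on the assumption that each line was a single read. The lines proved to be peaks, so each was weighted by its reads. Neither an hg19 annotation nor an hg19 sequence was used here. The files do not pair gene IDs with names, and 0 of the IDs matched a symbol in the reference table. Annotation classes other than the mitochondrial chromosome, annotated mRNA 3' ends, small nuclear RNAs, sequence motifs and all gene lists except the mitochondrial transcripts were therefore not analysed here. In that case the rule named the 20 loci present in all 3 replicates with the highest mean share of reads, and the 10 gene IDs with the highest mean share. It also named the 10 called gene IDs at each end with the smallest binomial p.

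Replicate agreement was the share of clusters that overlapped a cluster of another replicate by at least 1 nt on the same strand. It was set against 20 random placements in which each cluster was shifted by 1 to 10 kb. Spearman's rho and Pearson's r on log2(reads + 1) were computed across gene IDs for the 3 pairs of replicates; gene IDs are not independent replicates, so no p was taken from them. The mitochondrial list was compared with 10000 random lists of nuclear gene IDs of the same size, without the planned match on gene length and class, which needs an annotation.

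For the ends of transcripts a substitute was chosen after the lists had been seen. The listed span of a gene ID ran from its first to its last peak over all 3 replicates, for gene IDs with at least 5 loci. Reads in the last 10% of the span (3' end) were compared with reads in the first 10% (5' end). An exact two-sided sign-flip test over 3 replicates cannot give a p below 0.25. Per gene ID with at least 10 reads at both ends together, summed reads were compared by an exact two-sided binomial test with Benjamini-Hochberg adjustment. A gene ID was called at an adjusted p below 0.05 with the same direction in every replicate with reads there. Its log2 ratio carries 0.5 reads added to each end. The ends of a listed span are not annotated transcript ends. An earlier look, made before this window was chosen, compared only the outermost peaks at 4 minimum numbers of peaks per gene ID. The outermost locus and the outer 20% were run as alternatives, so the direction depends on a window picked after several had been looked at. The strand comparison was also chosen after the lists had been seen.

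On simulated data, 1000 of 1000 intervals were assigned correctly by the overlap step. For the comparison of 3' with 5' ends, independent reads were simulated for 6383 gene IDs with 200 changed 4-fold. Of the changed IDs, 49.0% were called in the right direction, and 1 unchanged ID was called. Reads of 1 peak are not independent, so these rates do not carry over to the listed reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives collapsed repeated lines or kept peaks with p at or below the median of their list. Another thinned the reads of each peak to the lowest total and dropped peaks left with under 3 reads. Further alternatives changed the overlap, the windows and the minimums, and left out each replicate in turn. Bootstrap intervals in the closing part used 1000 resamples of gene IDs. Coordinates are 1-based hg19 positions. The version of the mitochondrial sequence is not given in the sources used here, so its coordinates hold only for the authors' version.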

Results

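RNA crosslinked to CSTF2tau was recovered from 3 biological replicates of BE(2)-C neuroblastoma cells. Replicate 1 had 105203 peaks with 736059 reads under 11152 gene IDs. Replicate 2 was the smallest, with 18346 peaks, 108434 reads and 5173 gene IDs, and replicate 3 had 78761 peaks, 387784 reads and 10788 gene IDs. Peaks were narrow, with a median width of 79, 72 and 69 nt, and shallow, with a median of 5, 4 and 4 reads. Signal was spread over many genes: the top 10 gene IDs held 8.30%, 10.1% and 5.52% of the reads. Regions are given by hg19 position and strand because the files do not pair gene IDs with names.

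The first comparison asked whether CSTF2tau was recovered at the same places in each replicate. Most gene regions came back in more than 1 replicate, but most exact positions did not. Of 13356 gene IDs, 4414 had peaks in all 3 replicates, 4929 in exactly 2 and 4013 in exactly 1. Of 172167 loci, 1530 were present in all 3 replicates, 13227 in exactly 2 and 157410 in exactly 1. The 1530 loci held 4.54%, 15.4% and 5.04% of the reads of replicates 1, 2 and 3.

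Position overlap nevertheless exceeded random placement in each replicate. In replicate 1, 15.3% of clusters overlapped a cluster of another replicate (95% interval 15.1 to 15.5%), against a mean of 4.66% and a highest value of 4.84% over 20 random shifts. The share was 35.4% in replicate 2 (34.7 to 36.1%), against 11.1%, and 16.9% in replicate 3 (16.6 to 17.1%), against 5.21%. The mean was 22.5% ± 11.2 (SD, n = 3), and the excess over random shifts was 3.28-fold, 3.19-fold and 3.24-fold. Reads per gene ID correlated across gene IDs with a Spearman rho of 0.54 for replicates 1 and 2, 0.66 for 1 and 3, and 0.50 for 2 and 3. The matching Pearson r values were 0.57, 0.62 and 0.53. The reads of each peak were also thinned to the lowest total, and peaks left with under 3 reads were dropped. The mean rho then went from 0.57 to 0.27, and 291 loci were left in all 3 replicates. Only replicates 1 and 3 lost peaks this way, so the fall does not measure agreement at equal totals.

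Clusters with more reads were shared more often. The classes of reads were not matched on cluster width, and a wider cluster can overlap another more easily. In replicate 1 the shared percentage was 8.96% among clusters of 3 to 4 reads and 55.9% among clusters of 50 reads or more. In replicate 2 it was 25.9% and 88.6%. Replicate 3 had 10.3% for clusters of 3 to 4 reads, 81.7% for 20 to 49 reads, and 81.5% for 50 reads or more, the last over 27 clusters.

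**Figure D1:**
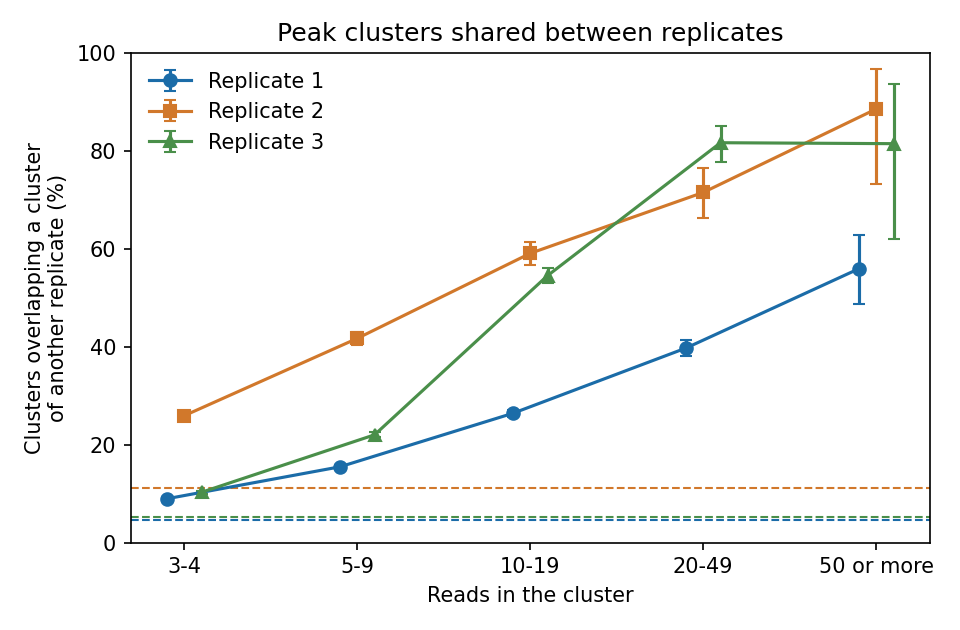
The vertical axis is the percentage of clusters that overlap a cluster of another replicate. The horizontal axis is the number of reads in the cluster, and bars are exact 95% intervals. Dashed lines are the mean of 20 random shifts of all clusters of a replicate. Random shifts were not run per class of reads, so the lines are no baseline for a single class. From the smallest class to clusters of 50 reads or more, sharing goes from 8.96% to 55.9% in replicate 1, from 25.9% to 88.6% in replicate 2 and from 10.3% to 81.5% in replicate 3.

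The strongest loci found in all 3 replicates lay on mitochondrial transcripts and in a few short nuclear regions. Of the 20 loci with the highest mean share of reads, 9 were on the mitochondrial chromosome. The first was 187 nt long, at chrM:9756-9942 on the plus strand, with 0.0781% ± 0.0664 of the reads (SD, n = 3; 0.0152%, 0.148% and 0.0714% in replicates 1, 2 and 3). Next were chrM:692-727 (+), 36 nt long, with 0.0730% ± 0.0870, and chrM:6358-6587 (+) with 0.0559% ± 0.0522. The most even locus was chrM:12335-12573 (+), with 0.0394%, 0.0378% and 0.0353%, a spread of 1.12-fold between the highest and the lowest.

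The first of the 11 nuclear loci was 86 nt long, at chr17:62223683-62223768 (+), with 0.112% of the reads in replicate 2 but 0.00217% and 0.00206% in replicates 1 and 3. A 109 nt locus at chr19:54711520-54711628 (+) had 0.0959% in replicate 2 and differed 176-fold between replicates. A short stretch of chr11 held 3 of the nuclear loci on the minus strand. They lay at chr11:2151224-2151421, with a mean of 0.0328% ± 0.0418, at chr11:2153077-2153288, with 0.0302% ± 0.0173, and at chr11:2153978-2154371, with 0.0269% ± 0.0305. All 3 carried the same gene ID, and the last was also listed under another. Replicate 2 had the highest share at 18 of the 20 loci, and without it the mean share of 18 loci was lower by over 1.5 times, with 0.00212% left at the chr17 locus and 0.00156% at the chr19 locus. Several gene IDs were listed at 3 of the 20.

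**Figure D2:**
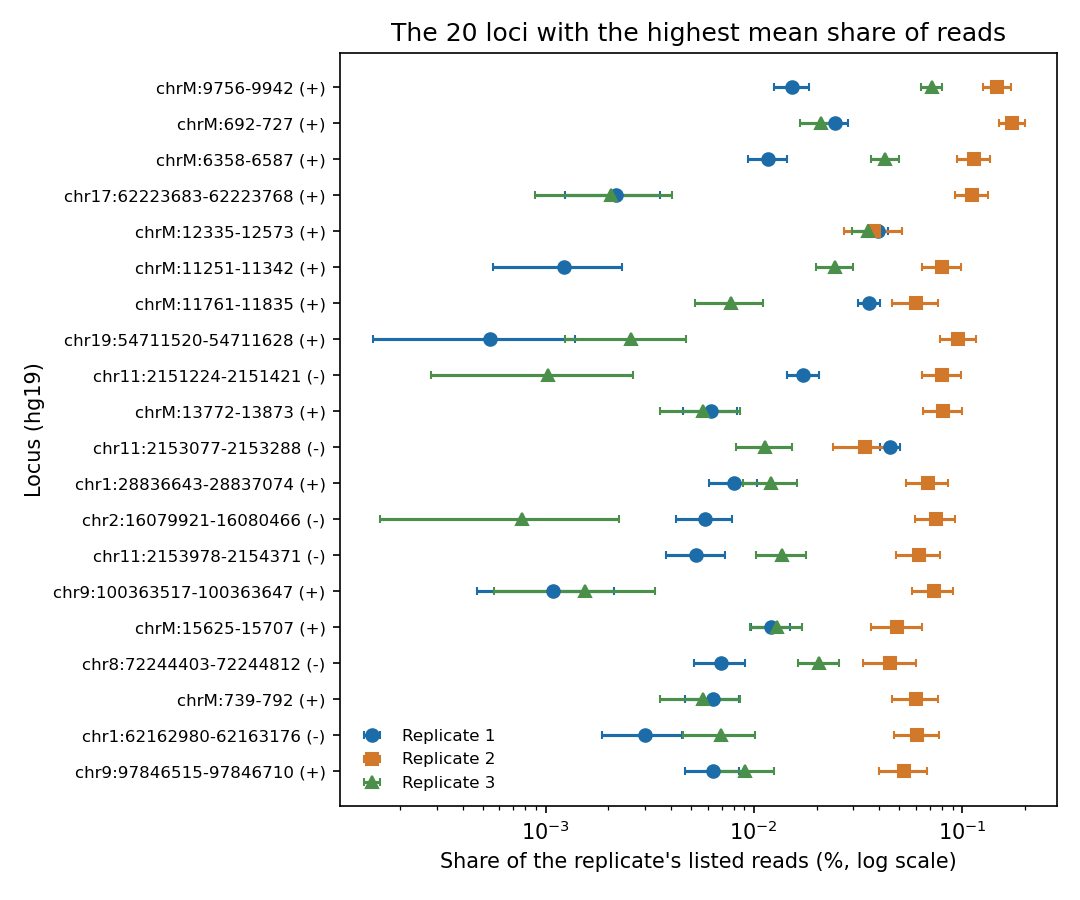
Each row is 1 of the 20 loci present in all 3 replicates with the highest mean share, and the horizontal log axis is the percentage of the replicate's listed reads; points are replicates and bars exact 95% intervals. Replicate 2 has the highest share at 18 loci, while chrM:12335-12573 has 0.0394%, 0.0378% and 0.0353%.

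By whole gene ID, the largest shares lay in long nuclear regions with many peaks each. A region of chr13 on the minus strand, chr13:107821338-108518283, held 1.76%, 2.55% and 1.59% of the reads, a mean of 1.97% ± 0.513 (SD, n = 3), in 1390, 351 and 625 peaks. The next, chr3:115521383-117715978 (-), held 1.46%, 2.04% and 1.32%, a mean of 1.61% ± 0.380. Further regions among the first 10 were chr4:113740306-114304950 (+), with 0.452% ± 0.120, and chr12:79258598-79845005 (+), with 0.452% ± 0.175. The region ranked 3 by mean share, chr8:31497351-32574522 (+), had 1.66% of the reads of replicate 1 in 1268 peaks, while its gene ID had no listed peak in replicates 2 and 3. Another gene ID that overlaps it had 179 and 211 reads at the same peaks in replicates 2 and 3, so the missing ID does not show that the region lacked signal.

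Mitochondrial transcripts, the one preset gene list that could be measured, took a small and variable part of the reads. Their share was 0.356% in replicate 1 (95% interval 0.343 to 0.370%), 2.67% in replicate 2 (2.58 to 2.77%) and 0.917% in replicate 3 (0.887 to 0.948%), a mean of 1.32% ± 1.21 (SD, n = 3), or 0.637% without replicate 2. Of 29 mitochondrial gene IDs, 11 had reads in all 3 replicates; leaving out replicate 1, 17 had reads in both others. The region with the highest mean, chrM:692-1011 (+), held 0.0310%, 0.674% and 0.0846% of the reads. On the minus strand, chrM:14144-14539 held 0.00394%, 0.381% and 0.217%. The median mean share per mitochondrial gene ID was 0.0117%, above all 10000 random nuclear lists, whose median was 0.00195%. Those lists were not matched on gene length or abundance, so this describes the libraries and is no test of binding.

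The replicates differed in the strand of their reads. In replicate 3, 63.2% of nuclear reads lay on the minus strand, against 48.8% in replicate 1 and 50.6% in replicate 2. The excess was spread over the genome: all 23 nuclear chromosomes of replicate 3 were above 50%, against 9 in replicate 1 and 10 in replicate 2. Compared with replicate 1, the minus-strand share of replicate 3 was higher on 22 of 23 chromosomes, by a median of 14.1 percentage points (exact two-sided sign test, p = 5.7e-06, adjusted p = 1.7e-05). It was higher than in replicate 2 on 21 of 23, by a median of 12.6 points (exact sign test, p = 6.6e-05, adjusted p = 9.9e-05). Replicates 2 and 1 differed by a median of 0.575 points (exact sign test, p = 1, adjusted p = 1). Peaks gave 61.0%, 48.5% and 50.8% in replicates 3, 1 and 2. Chromosomes are not replicates, and these tests compare the 3 libraries only.

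**Figure D3:**
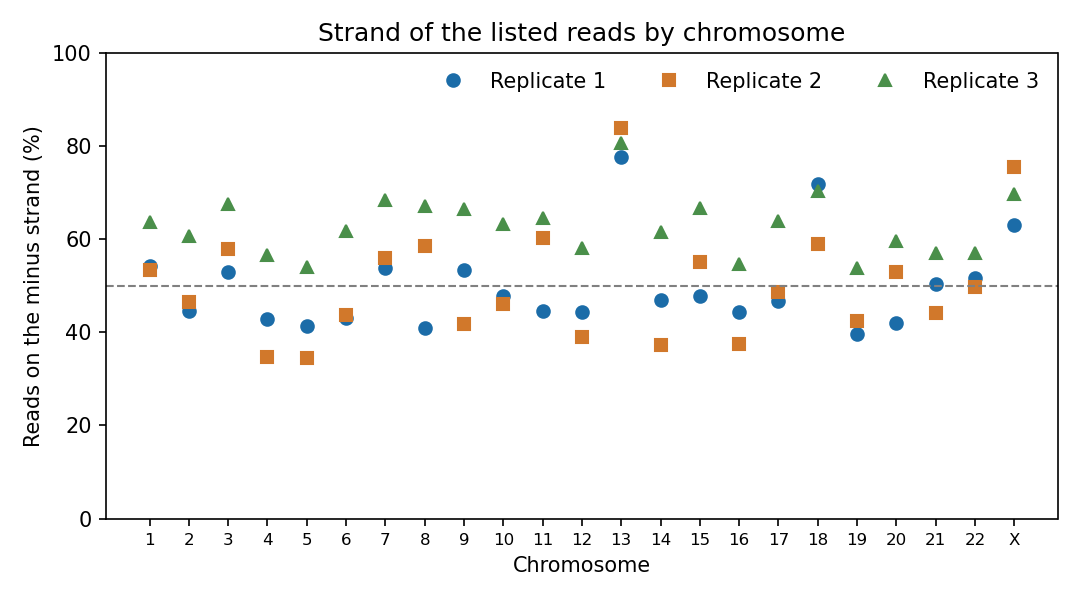
The vertical axis is the percentage of listed reads on the minus strand and the horizontal axis the chromosome; each point is 1 replicate and the dashed line marks 50%. All 23 chromosomes of replicate 3 lie above the line, against 9 in replicate 1 and 10 in replicate 2.

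CSTF2tau belongs to the factor that acts at mRNA cleavage sites, and the next comparison asked whether reads favoured the 3' end of gene regions. They did so only in replicate 2. The last 10% of the listed span held 26.9% of the reads of replicate 2 and the first 10% held 15.0%. In replicate 1 the shares were 15.7% and 17.8%, and in replicate 3 they were 14.0% and 16.6%. The log2 ratio of 3' to 5' reads over 7087 gene IDs was -0.18, 0.85 and -0.25 in replicates 1, 2 and 3, a mean of 0.14 ± 0.61 (SD, n = 3; exact sign-flip test, p = 1, smallest possible p 0.25). The mean changed sign without replicate 2 (-0.18) and with the outer 20% of the span (-0.07), and it was 0.41 with each gene ID weighted equally and 0.74 with the outermost locus alone, so no common direction was measured. Each span starts and ends at a listed peak, which by itself raises the outermost parts over the middle.

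**Figure D4:**
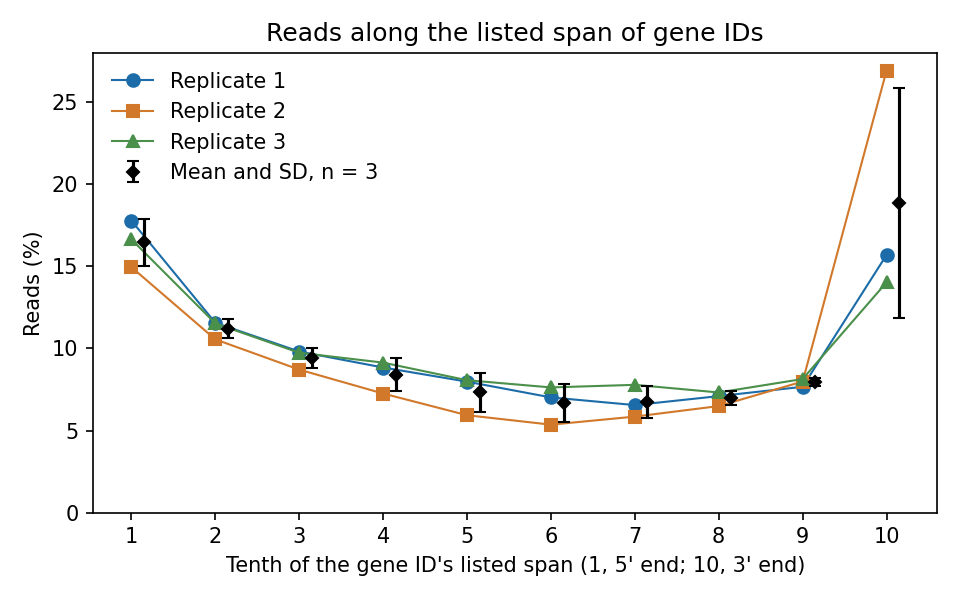
The horizontal axis divides the listed span of gene IDs into 10 parts from the 5' end (1) to the 3' end (10), and the vertical axis is the percentage of reads in each; lines are replicates and diamonds the mean with SD (n = 3). The last part holds 26.9% of the reads in replicate 2, against 15.7% and 14.0% in replicates 1 and 3.

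Single gene regions had strong differences between their ends, in both directions. Of 6383 gene IDs tested, 1162 were called with more reads at the 3' end and 899 with more at the 5' end. Among called gene IDs with reads in all 3 replicates, the numbers were 617 and 360; such calls need the direction of replicate 2, which leaned to the 3' end. At the 3' end, ENSG00000148120 (chr9:97490872-97849528, +) had 1242 reads against 25, a log2 ratio of 5.61, with 516 against 10 reads in replicate 1, 499 against 0 in replicate 2 and 227 against 15 in replicate 3. ENSG00000131711 (chr5:71404992-71505490, +) had 670 against 11, a log2 ratio of 5.87 (exact binomial test, adjusted p = 2.6e-179). Among the other 8 regions named at the 3' end, chr5:168089464-168724168 (-) had 753 reads against 34 and chr2:210335260-210598797 (+) had 502 against 4.

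At the 5' end, ENSG00000204442, the chr13 region with the highest share of reads, had 28 reads at the 3' end against 5148 at the 5' end, a log2 ratio of -7.50. Its replicates had 14 against 3343, 8 against 438 and 6 against 1367 reads. ENSG00000185565, the chr3 region with the next highest share, had 70 against 4213, a log2 ratio of -5.90. Without peaks listed under several gene IDs it had 70 against 793, a log2 ratio of -3.49, and was no longer called because the replicates differed in direction. The 10 regions named at the 5' end spanned 351 to 2195 kb, against 81.4 to 1551 kb for those at the 3' end. They included chr3:85008379-86103663 (+), with 21 against 944 reads, and chr13:66890612-67804453 (-), with 12 against 1016. The chr8 region listed only in replicate 1, chr8:31497351-32574522, was also among them, with 5 against 4138 reads.

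The tests over reads cover counting error only, since reads of 1 peak are not independent. When peaks were counted in place of reads, 219 gene IDs were called at the 3' end and 223 at the 5' end, so the excess of 3' calls was not seen. With only the outermost locus at each end, 143 and 56 gene IDs were called, ENSG00000148120 had 27 reads against 10 (exact binomial test, adjusted p = 0.059), and 11 of the 16 named regions that could be tested lost their call. Calls at the 3' and 5' end numbered 620 and 539 without replicate 1, 1148 and 1050 without replicate 2, and 1176 and 734 without replicate 3.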

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

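The tests on the strand excess and on gene IDs without peaks were chosen after those results had been seen; the tests on the overlap between replicates were set before their values were seen.

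The running numbers in the peak names had gaps, a feature that the reported comparisons did not use. Of the numbers up to the highest of each gene ID, 54.4% had no listed peak in replicate 1, 60.2% in replicate 2 and 52.6% in replicate 3. With no control library, this stood out only against an expectation of no gaps.

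The minus-strand excess of replicate 3 was examined first. Without the 100 gene IDs of highest mean share its minus-strand share was still 62.1% (bootstrap interval over genes 60.5 to 63.7%), which argues against a few genes taking most of the reads. Among the 4403 nuclear gene IDs listed in all 3 replicates, replicate 3 exceeded replicate 1 by 12.7 percentage points (11.1 to 14.3), which argues against a difference in the gene IDs listed. Between gene IDs of higher and lower mean share, the loss of plus-strand relative to minus-strand reads differed by 0.0039 on the log2 scale. The bootstrap interval was -0.15 to 0.15, which argues against a loss that grows with the reads of a whole gene ID. Gene IDs were not split by reads per position, so a step that saturates at single positions was not tested. An even loss of plus-strand reads in processing may remain as an explanation, and no biological explanation was tested.

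The next pattern was the absence of whole gene IDs from 1 replicate: of 5029 pairs of gene ID and replicate with at least 50 reads expected from the other replicates, 87 had none, 53 of 3101 in replicate 1, 13 of 296 in replicate 2 and 21 of 1632 in replicate 3. For 6 of the 87, the expected reads argue against too few listed reads in that replicate by counting error alone. These had at least 500 reads expected even from the lower of the other 2 shares. Expected reads come from listed peaks, so reads outside them and wider variation between replicates are not excluded. The rule of 500 reads leaves the other 81 undecided. It cannot reach a gene ID absent from 2 replicates, whose lower share is 0. By the mean of the other 2 shares, 10 of the 87 had at least 500 reads expected. Among them, the chr8 region listed only in replicate 1 had 902 expected in replicate 2 and 3227 in replicate 3. Beside the 81, 132 pairs had some reads but under 10% of the expected number. Of 40 absences whose peaks were shared with another gene ID, 25 (62.5%, exact interval 45.8 to 77.3%) had peaks of that other ID in the same replicate, which argues against a complete lack of bound RNA in those 25. A lower signal stays open, since the other ID had a median of 37.1% of its own expected reads there. The other ID had under 10% in 2 of the 25 and 50% or more in 11, with a highest value of 526%. Gene IDs may also have been left out at peak calling or listing in these 25 cases, which the tables do not decide, and no biological explanation was tested.

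The low overlap of peaks between replicates was the last pattern. In gene IDs listed in all 3 replicates, 36.3% of 2997 replicate 1 clusters with at least 20 reads overlapped a cluster of replicate 3. The exact interval of 34.6 to 38.1% argues against the totals of listed reads alone for these clusters. Sequencing depth was not known, so its part was not tested. Picking clusters by their reads in replicate 1 also favours clusters that are high there. In the other direction 67.2% of 396 such clusters of replicate 3 overlapped replicate 1. Such clusters of replicate 2 overlapped replicate 3 at 63.6% and replicate 1 at 39.8%. Those of replicates 3 and 1 overlapped replicate 2 at 53.8% and 19.6%. The observed sharing was at least 3.28 times that of random placement within the same gene's span in each of the 3 replicates. This argues against chance placement spread evenly over the span. Listed reads were not even along spans, and chance overlap within their dense stretches was not tested. Differences between the replicates in the RNA recovered or in peak calling may remain, and no biological explanation was tested.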

How the results depend on the processing

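All alternatives for the strand and end comparisons were chosen after the results had been seen; those for agreement and for the mitochondrial share were planned, except the limit to gene IDs in all 3 replicates. Of 81 alternative values of the main results, 60 stayed within a limit, 19 moved and 2 changed sign. The limit was 1 SD of the replicates, 1.5 times for counts, or the same sign for the end ratio. A limit of 1 SD is wide here. Clusters shared at 11.6% against 22.5%, and a mitochondrial share of 0.637% against 1.32%, both stayed within it. Thinned to the lowest total, without peaks left under 3 reads, the mean Spearman rho was 0.27 and 291 loci were in all 3 replicates. With peaks at or below the median p, these were 0.41 and 825. Gene IDs called at the 3' and 5' end with those peaks numbered 742 and 588. The outermost locus alone gave 143 and 56 calls, peaks in place of reads 219 and 223, and gene IDs listed in all 3 replicates 862 and 591. The end ratio was -0.074 with the outer 20%, 0.41 with equal weights and 0.74 with the outermost locus. Leaving out each replicate in turn gave ranges of 0.43 to 0.65 for rho, 3021 to 10559 for loci in all remaining replicates (fewer replicates raise this by construction), 11.6 to 15.1% for clusters shared (22.5% with all, and fewer partners lower it by construction), 0.637 to 1.80% for the mitochondrial share, 11 to 17 for mitochondrial gene IDs, -0.18 to 0.32 for the end ratio, 620 to 1176 for 3' calls and 539 to 1050 for 5' calls. Of 292 end ratios of named regions, 13 lost their call, 9 through the adjusted p and 4 because replicates differed in direction; 1 of the 13 changed sign, chr7:11411526-11871232 with 1.22 for the outermost locus alone. The wide spread between replicates hides changes in named shares, since 25 of 180 such shares differed by over 1.5 times, among them 18 of the 20 loci without replicate 2 and the chr8 region, at 0 without replicate 1. The cause of the other changes was not tested. Windows of 50 and 200 nt, the most distal 3' ends, random positions in exons, tags near annotated 3' ends, and everything on small nuclear RNAs and sequence motifs were not run for lack of an hg19 annotation and sequence; the peak edge in place of the middle could not move a share by chromosome.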

Other observations

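The comparisons of loci by replicate were chosen after the results had been seen. Loci were counted here once under each gene ID with at least 5 loci, so a locus listed under several IDs counted more than once. The position of loci along gene regions differed between replicates. Among loci of replicate 2 alone, 2713 lay in the last 10% of the listed span and 1696 in the first, a ratio of 1.60, against 0.799 and 0.823 for loci of replicates 1 and 3 alone. Loci of all 3 replicates had a ratio of 1.33, with 353 and 265 loci, but every one of them is also a locus of replicate 2. Among loci of replicate 2, and among loci outside it, being found again went with no detected difference in position. Replicate 1 loci found again in replicate 2 had a ratio of 1.34, against 0.799 for replicate 1 alone. Replicate 3 loci found again in replicate 2 had a ratio of 1.58, against 0.823 for replicate 3 alone. Both of these sets found again include the loci of all 3 replicates. Loci of replicate 2 found again in another replicate had a ratio of 1.47 (odds ratio 0.917 against those found once; Fisher's exact test, adjusted p = 0.188). Outside replicate 2, loci of replicates 1 and 3 found in both had a ratio of 0.847, with an odds ratio of 1.06 against replicate 1 alone (Fisher's exact test, adjusted p = 0.188) and 1.03 against replicate 3 alone (adjusted p = 0.472 by the same exact test). Neighbouring loci are not independent, so these p-values are too small.

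The mitochondrial minus strand also differed between replicates. It took 1.11% of the mitochondrial reads in replicate 1, 15.2% in replicate 2 and 23.9% in replicate 3, most of them in chrM:14144-14539.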
